A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

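Gene expression in 2 yeast hybrids was measured on 8 spotted cDNA arrays with 2 colours, 4 arrays per hybrid. On each array the RNA of a hybrid was hybridised together with a mix of RNA from its parental lines. Hybrid Sce2950 was set against a mix of sce2709 and sce2898, and hybrid Sce2965 against a mix of sce2713 and sce2902. Per the labels, the hybrid carried Cy5 on 2 arrays and Cy3 on 2 arrays of each hybrid, and the arrays of a comparison were independent replicates. The label that describes the cultures gives growth from a single colony to early log phase in half-strength YPD medium, hot acid phenol extraction of the RNA and direct labelling of the cDNA. Arrays were assigned to groups by the source of their second channel. No label ties an array to a named culture, so the p-values measure the spread between these arrays, part of which may be technical.

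The scanner files hold the intensity and the local background intensity of 13056 spots per channel, not normalized and not background subtracted, per the file headers. Per the file headers and the labels, channel 1 held the parental mix and channel 2 the hybrid on all 8 arrays, so a positive log ratio means more RNA in the hybrid. The authors' deposited series value table holds log2 ratios of hybrid over mix. Set against ratios recomputed from the scanner files by background subtraction and loess within print blocks, its columns had correlations between 0.962 and 0.997 and slopes between 0.922 and 0.991. Scale, direction and centring of that table were read from this comparison. The column medians were 0.00464, -0.00616, -0.00276 and 0.00835 for replicates 1 to 4 of hybrid Sce2950, and 0.000977, -0.00145, -0.00322 and 0.00333 for those of hybrid Sce2965. The authors' normalization software is not given in the sources used here. The table served as an alternative.

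The name field of the spots was filled for 0 spots, and no table that pairs spots with genes was used here. Features are therefore given by spot number. The 35 gene lists fixed beforehand could not be matched to spots and were not tested, and control spots were not told apart from gene spots. Spots with successive numbers, odd then even, were duplicates of one feature. Their brightness correlated at 0.957 to 0.995 on each array, against 0.167 to 0.204 for an even spot and the odd spot after it. Averaging these gave 6528 features. A feature was tested when measured on at least 3 arrays of each hybrid, which left 6526.

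Background was corrected by normexp with offset 50, log ratios were normalized by global loess within each array, and spots that the software had marked to be ignored were left out. limma 3.58.1 in R 4.3.3 was fitted to all 8 arrays with a coefficient for each hybrid and a dye coefficient shared by both, followed by empirical Bayes moderation. This left 5 residual degrees of freedom and added 5.5 prior ones. Benjamini-Hochberg adjustment over the 6526 features set the threshold at an adjusted p of 0.05. The limma tests were two-sided, and the permutation test of the overlap was one-sided. The comparisons were each hybrid against its mix, the difference of Sce2965 minus Sce2950, and the mean of both hybrids. A ratio tested against 0 does not tell the spread of the parental mix apart from that of the hybrid. If arrays shared a preparation of the mix, the spread between preparations is left out. The mixes differ between hybrids, so the comparisons share no control RNA. Figures were drawn with matplotlib 3.10.9 and correlations within blocks estimated with statmod 1.5.0.

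The fit was tested on simulated data for hybrid Sce2950 against its mix, over 6528 features. It recovered 93% of 100 features with a true log2 ratio of size 1 and 28% of 100 features with one of size 0.5, with 6 false calls. The changed features were all brighter than the median, and no background was simulated. Noise was independent between arrays, with a dye effect common to all slides. The recovered shares therefore do not carry over to dim features or to arrays that correlate, as the later slides did.

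The rule for named features, fixed before the data were examined, took the largest log2 ratios in each direction among features past the threshold that went the same way on every array of the comparison. For the difference, the same way meant that the arrays of the hybrids did not overlap. Because no gene names were at hand, at most 2 features that rose and 2 that fell are printed per comparison, and the parts of the rule that fill up short lists or name genes by symbol were not applied.

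Median spot intensity lay between 115.5 and 312.7 for the mix and between 159.4 and 454.8 for the hybrid. Between 0 and 59 spots per array were marked to be ignored. Up to 168 spots on an array had a signal of 0 in a channel, and at most 4 reached 65000 in a channel. The slides came from 3 series by the first digits of their numbers. One early series held only replicates 1 and 2 of Sce2950, another held only replicates 1 and 2 of Sce2965, and the later series held replicates 3 and 4 of both. The median local background was 0 in each channel of the early slides except the hybrid channel of replicate 2 of Sce2965, where it was 2.597, and lay between 56.28 and 65.88 on the later ones. The SD between duplicate spots, on the log2 scale, was 0.188 to 0.254 on the early slides and 0.0611 to 0.0644 on the later ones. The number of arrays limits the precision.

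The alternatives covered background correction, normalization within and between arrays, a filter on the dimmest 25% of features, ignored spots, duplicate spots kept separate, array weights, the dye term, each hybrid fitted alone, the slide series, a replicate block, the authors' table, each replicate left out, a threshold of 0.01 and a minimum of 1.5-fold. A dye term of its own for the later slides and a fixed block for slide series were added after the data were seen.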

Results

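Transcript levels of 2 hybrid strains of Saccharomyces cerevisiae, Sce2950 and Sce2965, were compared with those of their own parents on cDNA arrays. Each hybrid came from parental lines that had adapted to different environments. Because the reference was a mix of RNA from the parents, each ratio sets the hybrid against the blend of its parents. The series describes its question as the effect on expression of bringing such genomes together, and not the expression changes of adaptation itself. There were 4 arrays per hybrid, 2 in each dye orientation, and 6526 features were tested, each printed as 2 spots. Features are given by spot number because the array files do not pair spots with genes. Values are log2 ratios of hybrid over mix, so 1 is a doubling.

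The first comparison asked which features of hybrid Sce2950 departed from the mix of its parents. There were 12 features above the mix and 0 below it past an adjusted p of 0.05 in limma. Their log2 ratios lay between 0.73 and 1.26, with a median change of 2.16-fold, and all 12 were above the mix on all 4 arrays. The feature at spots 10209 and 10210 was highest, at 1.26 ± 0.192 (SD, n = 4; limma adjusted p = 0.00659), or 2.39-fold. The feature at spots 10991 and 10992 followed at 1.22 ± 0.34 (SD, n = 4; limma adjusted p = 0.00659), or 2.33-fold. At an unadjusted p under 0.05 there were 148 features, fewer than 5% of those tested. With print-tip loess 17 features were above the mix and 2 below. Array weights gave 47 above and 10 below, separate duplicate spots 23 and 2, and the slide series with both hybrids alone 53 and 21. Most other settings gave 0 below. With median centring 2 passed, and with normexp at offset 0 the count was 0. At that offset the features at spots 10209 and 10991 stood at 1.43 and 1.28 (limma adjusted p = 0.138 each), so these calls ended with no smaller ratio. The count was 0 without replicate 1, without replicate 2 or without replicate 4 of this hybrid, and 5 without replicate 3.

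In hybrid Sce2965 the departures went both ways, with 13 features above the mix of its parents and 15 below. The sizes of these log2 ratios lay between 0.63 and 1.10, and all 28 features went the same way on all 4 arrays. The features at spots 919 and 920 and at spots 6163 and 6164 rose most. The former stood at 1.10 ± 0.724 (SD, n = 4; limma adjusted p = 0.0281) and the latter at 1.06 ± 0.0652 (SD, n = 4; limma adjusted p = 0.00682), so their replicate spreads were far apart. The call at spots 919 and 920 was lost in 15 of 26 other settings, with 0.74 without background subtraction (limma adjusted p = 0.851), 0.90 with plain subtraction (limma adjusted p = 0.848) and 1.01 in the authors' value table (limma adjusted p = 0.24). Among those that fell, spots 6263 and 6264 stood at -1.02 ± 0.381 (SD, n = 4; limma adjusted p = 0.0208) and spots 2027 and 2028 at -1.02 ± 0.157 (SD, n = 4; limma adjusted p = 0.00682), each 2.03-fold below the mix. The former lost its call in 11 of 26 other settings, at -0.66 with print-tip loess (limma adjusted p = 0.352) and -0.61 in the authors' value table (limma adjusted p = 0.857). The latter lost it in 5 of 26. At an unadjusted p under 0.05 there were 362 features, a share of those tested just above 0.05. The count was 84 with print-tip loess, with 44 above and 40 below. It was 0 with median centring, with normexp at offset 0, when this hybrid was fitted alone, without its replicate 3 or without its replicate 4. It was 5 without its replicate 1 and 16 without replicate 4 of Sce2950.

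The hybrids were then compared with each other, to ask whether a feature departed from the parental mix by a different amount in each. There were 26 features that differed, 21 of them lower in Sce2965 and 5 higher. At an unadjusted p under 0.05 in limma there were 221, a share of those tested below 0.05. Leaving out 1 array gave 10 features without replicate 1 of Sce2950 and 11 without replicate 4 of either hybrid, in each case with 0 higher in Sce2965. It gave 15 without replicate 3 of Sce2965, and 17 and 16 without replicates 2 and 3 of Sce2950. Of the 21, 18 were above the mix on all 4 arrays of Sce2950 and below it on all 4 arrays of Sce2965. Among these 18 the median log2 ratio was 0.97 in Sce2950, or 1.96-fold above the mix, and -0.96 in Sce2965, or 1.94-fold below. The feature at spots 6263 and 6264 was 1.18 ± 0.385 in Sce2950 and -1.02 ± 0.381 in Sce2965 (SD, n = 4 each; limma adjusted p of the difference = 0.0011). Spots 7349 and 7350 gave 1.19 ± 0.387 and -1.01 ± 0.526 (SD, n = 4 each; limma adjusted p of the difference = 0.00123). In the authors' value table the differences of these features were -1.83 (limma adjusted p = 0.193) and -1.26 (limma adjusted p = 0.674), so both calls were lost. With print-tip loess the call at spots 7349 and 7350 was lost, at -1.46 (limma adjusted p = 0.0966). In the other direction, spots 11281 and 11282 were at -0.28 ± 0.101 in Sce2950 and 0.83 ± 0.15 in Sce2965 (SD, n = 4 each; limma adjusted p of the difference = 0.0107), and spots 6163 and 6164 at -0.02 ± 0.273 and 1.06 ± 0.0652 (SD, n = 4 each; limma adjusted p of the difference = 0.0201). These calls were lost in 9 and 14 of 27 other settings.

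**Figure D1:**
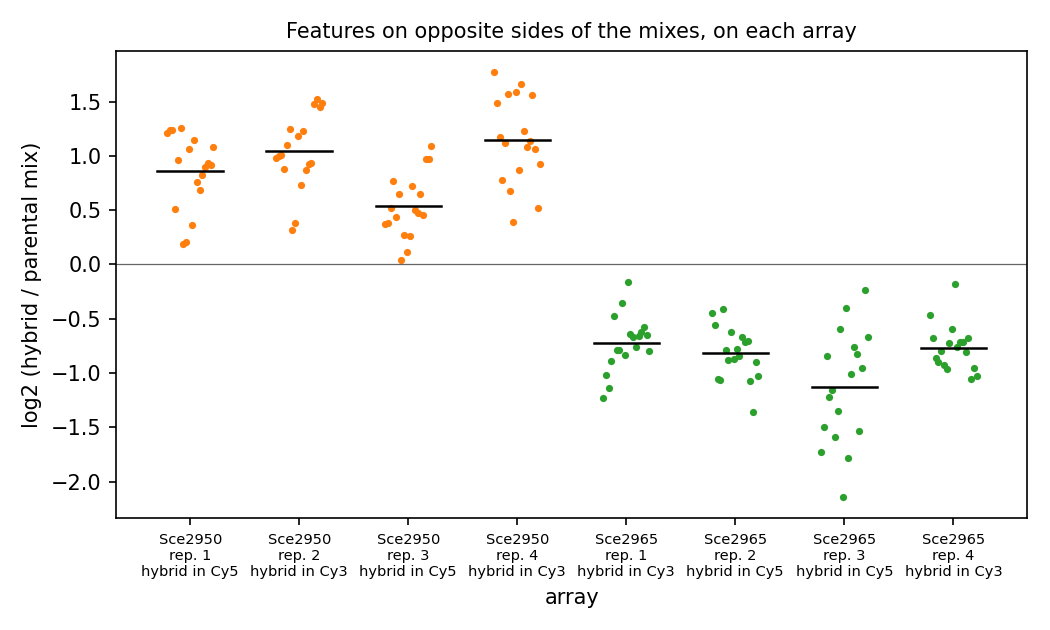
Log2 ratio of hybrid over parental mix (vertical axis) on each of the 8 arrays (horizontal axis) for 18 features. These differed between the hybrids and lay above the mix on all arrays of Sce2950 and below it on all of Sce2965. Each point is a feature and each black line the mean of the array, which lies between 0.536 and 1.15 for Sce2950 and between -1.13 and -0.725 for Sce2965.

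The 18 features were chosen by their signs and by the threshold on the difference, so both the separation in the plot by array and the size of the difference follow in part from the choice. A further 10 features had the same order of signs and did not pass. The reverse order, below the mix on all arrays of Sce2950 and above it on all of Sce2965, was shown by 3 features that passed and 18 that did not. With independent signs on every array, 0.391% of features would show each order, and 0.429% of all tested features showed the first. Arrays of the later slides correlated by dye orientation, so 0.391% need not be the share that chance gives here. The 18 lay in 13 of the 48 print blocks, with 0 printed next to each other, and were bright, with a median mean log2 intensity of 11.3 against 7.64 for all features. On the slide series that held both hybrids, the median difference of the 18 was -1.80, and between the early slides it was -1.92. A fit to the series with both hybrids alone has 2 arrays per hybrid and a dye term. This leaves few residual degrees of freedom, so its counts lean on the prior spread. Its arrays also helped to give the 26 above, so shared features are no independent support. In that fit 125 features passed, 67 higher in Sce2965 and 58 lower, and 26 of them were shared with the 26 above. The majority of lower features was also absent with array weights, at 39 higher and 40 lower, and with a replicate block, at 32 each way. With slide series as a fixed block 0 features passed in limma and 52 had an unadjusted p under 0.05. Neither early series held both hybrids, so with this block the difference rests on the later slides alone. The loss of calls therefore does not show an effect of the slide series. The differences at spots 6263 and 6264 and at spots 7349 and 7350 were then those of the later slides, -2.36 and -2.46. Without the block they were -2.21 and -2.20, so these calls ended with no smaller difference. With print-tip loess 12 features were higher in Sce2965 and 20 lower, and with median centring 0 were higher and 15 lower.

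The mean of both hybrids was tested next, and a feature past the threshold for the mean need not depart in each hybrid. For the mean 3 features passed, 2 above the mixes and 1 below. At an unadjusted p under 0.05 there were 285, a share of those tested below 0.05. The feature at spots 10991 and 10992 was above the mix on all 8 arrays, at 1.22 ± 0.34 in Sce2950 and 0.67 ± 0.142 in Sce2965 (SD, n = 4 each; limma adjusted p of the mean = 0.00659), and in Sce2965 taken singly it missed the threshold (limma adjusted p = 0.0705). The feature at spots 3501 and 3502 was below it on all 8, at -0.48 ± 0.352 and -0.80 ± 0.244 (SD, n = 4 each; limma adjusted p of the mean = 0.026), and in Sce2950 taken singly it missed the threshold (limma adjusted p = 0.418). The remaining one was at spots 10209 and 10210, named because the count is small. It stood at 1.26 ± 0.192 in Sce2950 and 0.13 ± 0.317 in Sce2965 (SD, n = 4 each; limma adjusted p in Sce2965 = 0.939), and differed between the hybrids by -1.13 (limma adjusted p = 0.0235). So 0 of the 3 passed in both hybrids taken singly. The call at spots 3501 and 3502 was lost in 12 of 25 other settings and that of the mean at spots 10991 and 10992 in 2 of 25. The count was 30 with print-tip loess, 15 in each direction. It was 0 without replicate 4 of Sce2950 and 1 when any one of replicates 1 to 3 of Sce2950 or replicates 3 and 4 of Sce2965 was left out. It was 5 after scaling between arrays, with 2 above and 3 below, and 1 above with median centring.

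Across the 6526 features the fitted ratios of the hybrids had a Pearson correlation of -0.00486 and a Spearman correlation of 0.0706. Features are not independent replicates. The Pearson correlation lay between -0.14 and 0.106 with each array left out in turn, and was -0.224 with slide series as a random block. Among called features 0 were above the mix in both hybrids and 0 below in both. By contrast, 10 of the 12 features above the mix in Sce2950 were among the 15 below it in Sce2965, where independent lists would share 0.0276. None of 10000 permutations of the feature labels gave as large an overlap (permutation p = 1e-04, one-sided, the smallest they can give). Both lists rest on one pooled estimate of each feature's spread, which the permutation does not keep. The overlap was 0 when each hybrid was fitted alone, with normexp at offset 0, with median centring, and at an adjusted p of 0.01. It was also 0 without replicate 1, 2 or 4 of Sce2950 or without replicate 3 or 4 of Sce2965. In all of these settings except the adjusted p of 0.01, no feature passed in Sce2950, in Sce2965 or in both. An empty list fixes the overlap at 0, so these values do not show that ratios lost their opposite signs. The overlap was 2 without replicate 1 of Sce2965 and 3 without replicate 3 of Sce2950 or after scaling between arrays. It was 4 with plain background subtraction or in the authors' value table. At an unadjusted p under 0.05 in each hybrid, 21 features had this order against 2.53 for independent lists, while 9 were above in both against 3.13, 9 were below in both against 1.14, and 7 were below in Sce2950 and above in Sce2965 against 1.41. All 4 combinations of signs thus exceeded the count for independent lists.

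**Figure D2:**
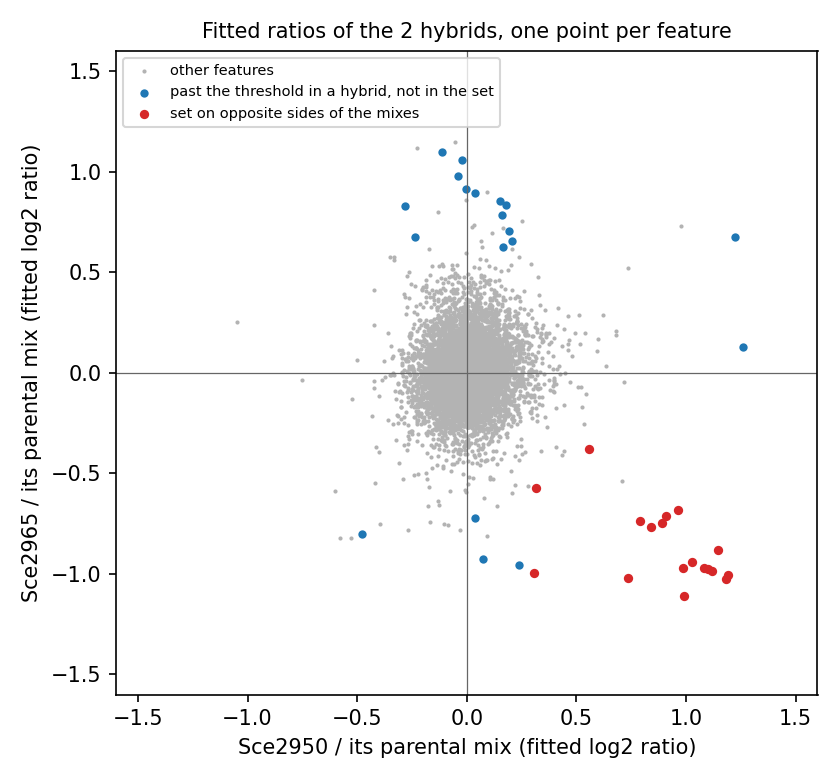
Fitted log2 ratio to the parental mix in Sce2950 (horizontal axis) and in Sce2965 (vertical axis), one point per tested feature. Red points are the 18 features that differed and lay above the mix in Sce2950 and below it in Sce2965, at medians of 0.97 and -0.96. The 3 features that differed in the reverse order are not in red. Blue points are features past the threshold in at least one hybrid and outside the red set.

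Each hybrid was measured on 2 slide series, which allowed a comparison of its ratios across slides. The mean ratios of Sce2950 on its early and later slides correlated at 0.363 across features, and those of Sce2965 at 0.295. Means of different hybrids correlated between -0.0595 and 0.0358. These are Pearson correlations. By Spearman correlation the values were 0.238 for Sce2950 and 0.206 for Sce2965, and between -0.0516 and 0.118 for different hybrids, so the gap was smaller by rank.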

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

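The tests of a difference between the crosses, of the dye pattern and of wrongly recorded channels, and the counts of splits with a separate dye term, were chosen after the results were seen; the others were written down beforehand.

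The hybrids differed in 26 features by the limma test of the difference itself. Among features named in the text, the log2 difference of Sce2965 minus Sce2950 was -1.13 at spots 10209 and 10210, 1.08 at spots 6163 and 6164, -2.21 at spots 6263 and 6264, -1.75 at spots 2027 and 2028, 1.11 at spots 11281 and 11282, and -2.20 at spots 7349 and 7350.

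The pattern most worth following is the group of 18 features above the mix in Sce2950 and below it in Sce2965, with a median difference of -1.85. A misfit of the loess curve at the bright end would shift other features of that brightness too, but the 243 features outside the group nearest in brightness had a median difference of 0.022. The 66 features printed next to the group had a median of -0.086, with 43 of them below 0. This argues against a position effect of the group's size that neighbours share whatever their brightness. Neighbours were not matched on brightness, so a misfit of bright features within print blocks is not excluded. With print-tip loess the differences at spots 6263 and 7349 were -1.91 and -1.46, against -2.21 and -2.20 with global loess. The count of features lower in Sce2965 was 20 with print-tip loess and 21 with global loess. The 20 features lowest on the early slides alone, of which 15 belong to the 18, had a median difference of -1.74 on the later slides, with 19 of 20 below 0; a difference between the crosses or between their parental mixes is a candidate explanation. Whether the hybrid or the mix of its parents sets the ratio stays open, since each hybrid was measured only against its own mix.

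The second pattern is the dye: on the later slides arrays of opposite dye orientation correlated between -0.604 and -0.377 and arrays of the same orientation, from different hybrids, at 0.577 and 0.62. The opposite orientations of the early slides also anticorrelated, at -0.288 for Sce2950 and -0.331 for Sce2965, but with print-tip loess these were 0.0137 and -0.084, while those of the later slides lay between -0.587 and -0.322. A dye bias of single features common to all slides would make the dye components of early and later slides correlate. The component of the later slides correlated at -0.13 with that of the early Sce2965 slides and at 0.099 with that of the early Sce2950 slides. These components came from global loess. With print-tip loess the early anticorrelation largely vanished, so the low correlations cannot decide on such a bias. Channels recorded the wrong way round are argued against by the lowest correlation of a later array with the mean of the same hybrid's early arrays, which was 0.091. A dye bias that differs between slide series stays open and was not tested, and no biological explanation was tested.

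Of the 35 splits of the arrays into groups of 4, 3 gave at least the 26 features of the real one, and the highest other gave 928, so chance is not excluded for that count. Both larger splits part the later slides by dye orientation, and calls many times the real count point to a structure of the arrays. Within the series that held both hybrids 125 features passed, with few residual degrees of freedom. With the fixed block for slide series, where the difference rests on the same arrays, 0 passed. With a separate dye term for the later slides, 5 of 35 splits gave at least the real 28, with a highest other of 956. For the mean of both hybrids, 7 of 100 sign patterns gave at least the real 3 features, with a highest other of 525. With the separate dye term it was 8 of 100, where the real count was again 3 and the highest other 734. Without that term, the pattern with 26 features is the difference between the hybrids. The others, with 7, 39, 186, 271 and 525 features, part the later slides by dye orientation. Such patterns carry structure of the arrays, so their count cannot decide on chance, and chance is not excluded. For each hybrid the 8 sign patterns are too few for a share under 0.05. The real pattern gave 12 features in Sce2950 and 28 in Sce2965, the highest other gave 0 in each, and 1 of 8 patterns reached the real count in each.

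Among 28 groups of 4 arrays examined, 2 held an array far from the rest, and chance gives about 1 in 20. At spots 6263 and 6264, replicate 3 of Sce2965 stood at -1.59 against -0.925 to -0.789 on the other arrays. The median hybrid signal of replicate 4 of Sce2950 was 309.4 against 198.5 to 210.4. This was a later slide with the hybrid in Cy3. On the later slides the median signal lay between 297.1 and 327.8 in Cy3 and between 198.5 and 248.2 in Cy5, so the value was in the range of its dye there.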

How the results depend on the processing

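The separate dye term for the later slides and the fixed block for slide series were chosen after the data were seen. Counts below are of features past the threshold for Sce2950 (12 as reported), Sce2965 (28), the difference (26), the mean (3) and the overlap of features above the mix in Sce2950 and below it in Sce2965 (10); counts not given were within 1.5 times, and the cause of each change was not tested unless stated. No background subtraction gave 1 for the mean. Plain subtraction gave 11 for Sce2965 and an overlap of 4. Normexp with offset 0 gave 0, 0, 11, 0 and an overlap of 0, with 108, 314 and 232 features at an unadjusted p under 0.05 in limma for Sce2950, Sce2965 and the mean. Print-tip loess gave 19, 84 and 30 for the mean. Median centring gave 2, 0, 15, 1 and an overlap of 0, with 183 at an unadjusted p under 0.05 for Sce2965. Scaling between arrays gave 10 for Sce2965, 5 for the mean and an overlap of 3. Leaving out the dimmest 25% of features gave 47 for Sce2965 and 8 for the mean. Separate spots gave 25, 87, 44 and 37. Array weights gave 57, 130, 79, 97 and an overlap of 16. No dye term gave 1 for the mean. Each hybrid fitted alone gave 0 for Sce2965, with 194 at an unadjusted p under 0.05, and an overlap of 0. The random block for slide series, with an estimated correlation of -0.216, gave 23, 70, 63 for the mean and a correlation of the hybrids of -0.224. The series with both hybrids alone, 2 arrays per hybrid and so few residual degrees of freedom, gave 74, 245, 125, 184 and an overlap of 17. The authors' value table gave 17 for the difference, 14 for the mean and an overlap of 4. An adjusted p of 0.01 gave 5, 3, 13, 1 and an overlap of 0, by its construction. The separate dye term gave 50 for Sce2965. The fixed block for slide series gave 0 for the difference, which then rests on the later slides alone.

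The replicate block gave 64 features for the difference, 32 higher and 32 lower in Sce2965 against 5 and 21 as reported, and all 26 were among them. Deviations of same-numbered arrays from their group means correlated at -0.111, 0.0548, 0.663 and 0.655 for numbers 1 to 4, so the numbers were not taken to pair the samples; numbers 3 and 4 also shared slide series and dye orientation. An earlier form of this check took the dye term out as well and gave 0.225, 0.385, 0.506 and 0.529, each above 0.1; it was set aside before the block was fitted, because taking out a shared dye term alone gives independent arrays correlations of 0.2 for numbers 1 and 2 and -0.2 for numbers 3 and 4.

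Leaving out each replicate in turn gave 0 to 14 features for Sce2950, 0 to 28 for Sce2965, 10 to 25 for the difference, 0 to 4 for the mean and an overlap of 0 to 11. For Sce2950 the count was 0 without its replicate 1, 2 or 4 and 5 without its replicate 3. For Sce2965 it was 5 without its replicate 1, 0 without its replicate 3 or 4, and 16 without replicate 4 of Sce2950. The difference fell to 10, 17, 16 and 11 without replicates 1 to 4 of Sce2950, and to 15 and 11 without replicates 3 and 4 of Sce2965. The mean was 1 without replicates 1, 2 or 3 of Sce2950 or replicates 3 or 4 of Sce2965, and 0 without replicate 4 of Sce2950. The overlap was 0 without replicates 1, 2 or 4 of Sce2950 or replicates 3 or 4 of Sce2965, where a list of calls was empty. It was 3 without replicate 3 of Sce2950 and 2 without replicate 1 of Sce2965. The correlation of the hybrids lay between -0.14 and 0.106, with a jackknife standard error of 0.168.

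The 12 named results kept their direction in all 314 values under these settings. They were chosen for going the same way on every array, so a reversal was hardly possible. The stricter threshold and the minimum fold also reuse the reported fit. Of the 314 values, 228 stayed past the threshold and 86 did not. The gene list alternative was not run, because spots were not matched to genes. Signal over background limits dim features, and it is unknown for the early slides, where the median recorded background was 0 except in the hybrid channel of replicate 2 of Sce2965, at 2.597.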
